A study of Drosophila melanogaster with 3 samples.

How the data were processed

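Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been run on whole Drosophila melanogaster embryos of both sexes, collected 0 to 24 h after laying, per the labels. The embryos came from a transgenic line that carries the Dip3 protein fused to GFP at its C-terminus, and DNA bound to the fusion protein was pulled down with an antibody against GFP. Chromatin had been sonicated to fragments of 200 to 800 bp, per the labels. The labels give 3 biological replicates of this 1 group, so no comparison between conditions was possible, and replicate numbers were taken from the labels.

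The authors' files are peak lists. Per the file headers, regions were called for each replicate on its own alignments and once more on the pooled alignments of the 3 replicates, each time together with 1 further file that all lists of a build share and that the control-normalised tracks also name. Per the file headers, the thresholded set was then made from the 3 replicate lists and the pooled list by the irreproducible discovery rate (IDR), a measure of how consistently a region ranks across replicates. On dm6 this set holds exactly the 3741 strongest regions of the pooled list, so a single peak in it need not be strong in every replicate. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. All lists exist for builds dm6 and dm3, per the labels. Each region carries a signal value that the authors' caller assigned, on a scale that differs between lists, so it served here to describe, rank and filter regions within a list. Each deposited region also carries a −log10 q value, which saturates at a maximum in each list. The deposited replicate lists are relaxed lists that include background by design, and those of dm6 hold 30000 regions each.

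Sequencing depth was unknown, because peak lists carry no read counts. Intervals on shares are exact Clopper-Pearson 95% intervals, intervals on odds ratios use the log method, and both cover counting error only. The control sample named by the labels was not analysed here, and neither were the signal tracks.

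All positions are on dm6 and are counted from 1. The sequence was Release 6 of the genome and the annotation was Ensembl release 115 on BDGP6 patch 54. The ends of all regions were checked against the lengths of the chromosome arms. The dm3 lists were used for counts and overlaps among themselves. A promoter was the 500 bp on either side of any of 19607 annotated starts of protein-coding genes, and other summits were assigned in the order 5' UTR, 3' UTR, coding exon, non-coding exon, intron, intergenic. Background regions were the 11590 regions in the lower 50% of the pooled relaxed list that overlapped no IDR peak. A further set held 10000 random positions.

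A replicate's top list held its 3741 strongest regions, as many as the IDR set. Overlap of the top 1000 regions between replicates was tested one-sided against 1000 draws of random regions from the other replicate's list, with 1 bp as the minimum overlap. Locations, chromosomes and gene lists were tested with two-sided Fisher's exact tests. Peak strength by location was tested with a two-sided permutation test with 100000 resamples. Motifs were searched on both strands in windows of 101 bp centred on the summit and in windows of the same length 500 bp to a randomly drawn side, and were compared with the exact McNemar test. The search for words of 6 and 8 bases used the same windows. The Benjamini-Hochberg method adjusted p-values over the 25 gene lists, the 5 non-coding classes, the 20 motifs and each word length. Peaks and genes are not independent replicates, so these p-values describe the lists and not the spread between embryo collections. Precursor microRNAs were taken as non-coding genes named mir, since the annotation used has no such class. Of 970 list members, 3 symbols found no single match, namely nos, which is a synonym of more than 1 gene and here meant nanos, dys, which meant dysf, and Dorsocross1, which meant Doc1, already in its list. The name pattern for ribosomal proteins missed RpL37-1 and RpL37-2.

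The named peaks were chosen by a rule fixed before the data were examined. It takes the 25 IDR peaks with the highest signal that overlap the top list of every replicate, each named by the nearest protein-coding start. It adds the gene of the profiled protein, up to 4 bound members of each gene list with the highest signal, and the 10 words of each length with the largest ratio among those present in at least 2% of summit windows. Gene lists, motifs, tests and alternatives were also fixed before the data were examined. The alternatives were other promoter windows (200 and 1000 bp), other overlap criteria, other numbers of top regions, stricter peak sets, other backgrounds, other window lengths and flanks, starts of all gene classes, the most upstream start of each gene, the dm3 lists, and each replicate left out in turn. For IDR peaks, leaving a replicate out meant keeping those in both other top lists. The pooled list behind them still held the reads of that replicate. An alternative for motifs, in which each summit window was shuffled with the counts of neighbouring base pairs kept, the chromosome test without each replicate, and the gene lists completed with the missed members were chosen after seeing the data.

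The statistical functions were tested on simulated data. For the overlap of top regions, 2 lists made to share 70% of their top 1000 returned 70%. For gene lists, a list of genes with a raised share was found in 100% of 50 simulations, and 0.333% of 1200 lists without a raised share were called. For the search for words of 8 bases, which covered 32896 words, 0 were called in windows with nothing planted. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.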

Results

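The data were peak lists from ChIP-seq of GFP-tagged Dip3 in whole fly embryos, in 3 biological replicates of 1 group. Dip3 is the product of the gene Dlip3, a protein of the MADF and BESS domain family known as an interaction partner of Dorsal, the Rel-family factor that patterns the dorsoventral axis. The lists show where in the genome tagged Dip3 was recovered. The IDR set held 3741 peaks on dm6, with signal values between 85.1 and 2760 and a median of 141. Signal values are the authors' own and are compared here only within a list. Sequencing depth was unknown. At a q value of 0.01 or less, replicates 1, 2 and 3 listed 2480, 3226 and 8812 regions.

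Dip3 was found mostly at promoters, and there mainly just upstream of the start. Of the 3741 IDR summits, 2147 (57.4%, 95% interval 55.8 to 59.0%) lay within 500 bp of a protein-coding start, against 17.4% of 11590 background regions and 11.9% of 10000 random positions. Introns held 29.8% of the summits and intergenic DNA 9.65%. Coding exons held 9 summits (0.241%), against 13.2% of the background regions. Promoter summits sat at a median of −89 bp from the start, and 84.9% of them (1822 of 2147, or 48.7% of all IDR summits) were upstream of it. Background promoter summits were upstream in 49.6% of cases.

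The promoter share exceeded that of the background regions with an odds ratio of 6.39 (95% interval 5.89 to 6.93). The logarithm to base 10 of the one-sided exact p was −460.56. Within each replicate's own top list the promoter share was 51.1%, 53.1% and 62.3%, a mean of 55.5% ± 6.02 (SD, n = 3). The upstream bias of the promoter summits had an exact binomial p of 6.57e-252, and that of the background promoter summits had p = 0.738. Promoter peaks had a median signal of 150 and peaks elsewhere one of 130. The difference of 19.3 had a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give. A total of 1234 summits lay more than 1 kb from any protein-coding start and 186 (4.97%) more than 10 kb.

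**Figure D1:**
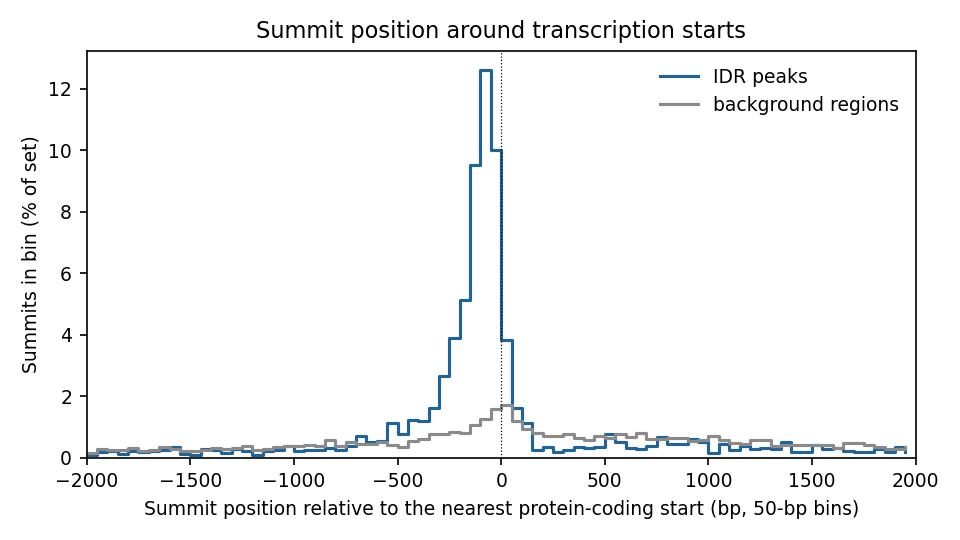
Position of summits relative to the nearest protein-coding start (x axis, bp, negative values upstream) as a percentage of each set per 50-bp bin (y axis), for IDR peaks (blue) and background regions (grey). The IDR summits pile up just upstream of the start, around their promoter median of −89 bp.

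**Figure D2:**
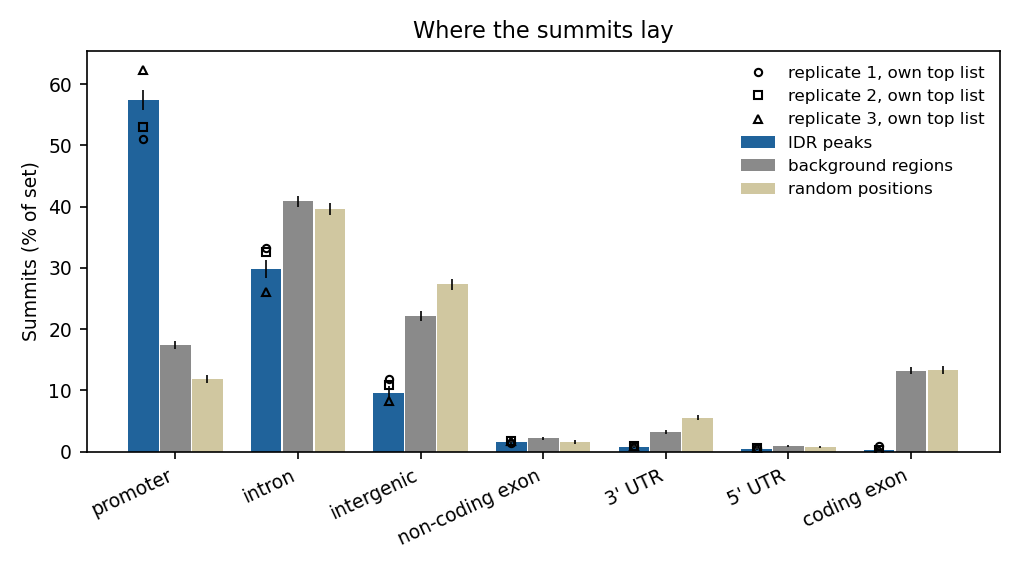
Share of summits by location (y axis, % of set) for IDR peaks, background regions and random positions (bars, with exact 95% intervals), with the top list of each replicate as open symbols. Promoters hold 57.4% of the IDR summits and coding exons 0.241%.

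The strongest site lay at CG14100 on 3L (19590432 to 19590813), at −104 bp from the start, with a signal of 2760. The next was at −38 bp from the start of Ugalt, which encodes a UDP-galactose transporter (X, 2703685 to 2704093, signal 2494.5). The peak ranked 3 (2L, 480905 to 481288, signal 2327) lay in an intron of ush, a cofactor of GATA factors, at −1404 bp from the start of cbt, a zinc finger transcription factor gene. An intronic peak in CG11050 (2L, 6612505 to 6612904) reached a signal of 1988. The Polycomb group gene ph-p carried a promoter peak (X, 2137180 to 2137546, signal 1749), as did mRpL41, a mitochondrial ribosomal protein gene (2R, 15217558 to 15217971, signal 1703). At Chro, which encodes a chromodomain protein of polytene interbands, the summit was 106 bp downstream of the start, in the 5' UTR (3L, 22878706 to 22879087, signal 1614). A pair of peaks on X (12751163 to 12751619 and 12752165 to 12752548) lay 5113 and 6054 bp from the start of CG4004, each in an exon of a different long non-coding RNA gene, the first of them Vinr, with signals of 1661.43 and 1247.

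The other named promoter peaks were those of Tcs5, CG1888, PNPase, CenG1A, Art3, GstE13, Shc, Pal1, CG31145, Atf3, Rubicon, eIF6 and CG5098. They include genes for an arginine methyltransferase (Art3), a bZIP transcription factor (Atf3) and a factor of ribosome biogenesis (eIF6). Their signals ran from 1081.56 at CG5098 to 1554 at Tcs5. The remaining intronic peaks were in CG32772 (signal 1468), Lk6 (1454) and CG9663 (1320). Of the 25 named peaks, 18 were at promoters, 15 within 300 bp upstream of the start. All 25 ranked 77 or better in every replicate. Rubicon, an autophagy regulator gene, ranked 72 and 77 in replicates 1 and 2 and 5 in replicate 3.

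At Dlip3 itself (2R, 18128494 to 18130246, plus strand) the IDR set held a peak from 18128577 to 18128966, with its summit 278 bp inside the gene, a signal of 163 and rank 1512. Replicate 3 listed this peak at rank 495. Replicates 1 and 2 listed no region over the gene, and their nearest summits were 2579 and 2572 bp from its start, at the promoter of stau. Between 18126105 and 18147857, a stretch of 21.8 kb, replicates 1 and 2 listed 0 regions and replicate 3 listed 12. The stretch spans Spn55B, Dlip3, the heat shock factor gene Hsf, the Polycomb-like gene Pcl and the poly(A)-binding protein gene pAbp, and part of EMRE. It held 4 IDR peaks, 3 of them at pAbp. Of the 5 IDR peaks within 15 kb of the Dlip3 start, 4 were absent from both lists, against 12 of the other 3736 (0.321%). The 15 kb were chosen after the values were seen.

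**Figure D3:**
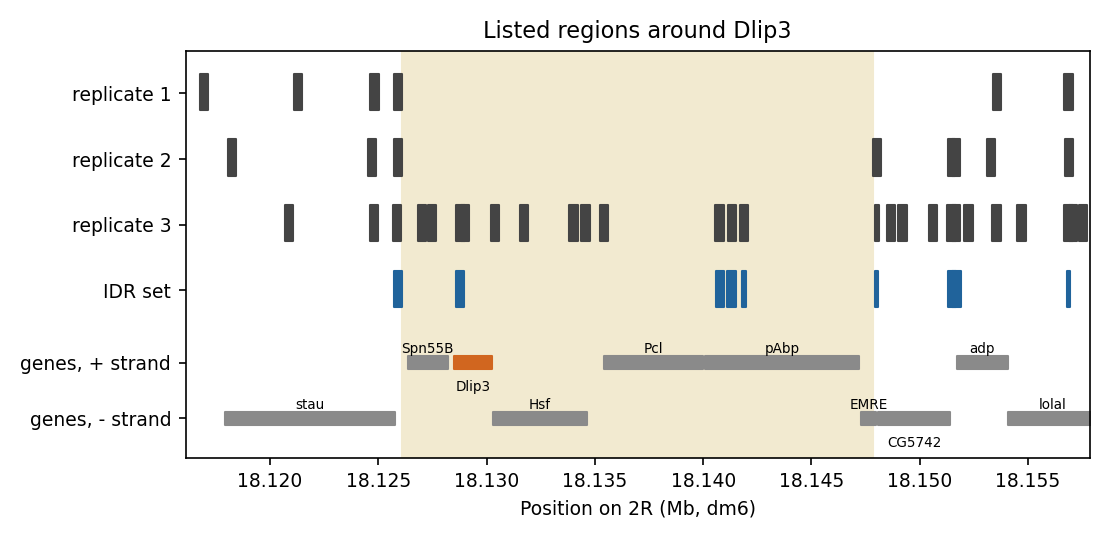
Map of 2R around Dlip3 (x axis, Mb on dm6) with the regions listed by each replicate (black), the IDR peaks (blue) and protein-coding genes by strand (grey, Dlip3 in orange). Shading marks the 21.8 kb in which replicates 1 and 2 listed 0 regions and replicate 3 listed 12.

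Most IDR peaks were also strong in single replicates. Part of this overlap is built in, since the IDR set is the 3741 strongest regions of the list from the pooled alignments of all 3 replicates. The top lists of replicates 1, 2 and 3 covered 81.5%, 85.2% and 77.6% of the IDR peaks, and 2195 (58.7%, 95% interval 57.1 to 60.3%) were in all 3. Peaks in all 3 made up 96.6% of the strongest quartile by signal and 9.95% of the weakest. A total of 37 IDR peaks (0.989%) were in no top list. Counting any overlap with the whole relaxed lists, 91.0% were in all 3. Under a reciprocal overlap of 50% the share in all 3 top lists was 43.5%.

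Among the top 1000 regions, replicates 1 and 2 shared 81.4%, replicates 1 and 3 shared 74.2% and replicates 2 and 3 shared 75.7%, a mean of 77.1% ± 3.82 (SD, n = 3 pairs). Random regions from the same lists shared at most 6.2%. The one-sided permutation p was 0.001 for each pair, the smallest that 1000 draws can give. Across IDR peaks matched in both lists, the Spearman correlation of the signal was 0.803 between replicates 1 and 2 (3430 peaks), 0.651 between 1 and 3 (3424 peaks) and 0.650 between 2 and 3 (3681 peaks). These coefficients are across peaks, which are not independent. Replicate 3 stood apart from the other 2 in this correlation, in promoter share and in the number of regions at a q value of 0.01 or less.

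Ribosomal protein genes were the most frequently bound group. A summit lay within 500 bp of a start for 67 of 86 cytoplasmic ribosomal protein genes (77.9%, 95% interval 67.7 to 86.1%). RpS27 (signal 688), RpL32 (616), RpL7 (550) and RpS20 (477) had the highest signals. The name pattern of this list missed RpL37-1, which was bound, and RpL37-2, which was not, and with both the count was 68 of 88 (77.3%, odds ratio 13.6). Over the whole genome 2834 of 13945 protein-coding genes (20.3%) had a bound start. A single summit can count for neighbouring genes alike, as it did for RpS27 and Nup37. Genes of the cell cycle and DNA replication were bound in 14 of 30 cases (46.7%), led by Dp, dpa, Mcm5 and Mcm2, of which the last 3 encode parts of the replicative helicase. Insulator, Polycomb and trithorax genes were bound in 8 of 18 cases (44.4%), with ph-p, Cp190, brm and Su(z)12 at the front. General transcription factor and RNA polymerase II genes were bound in 14 of 37 cases (37.8%), among them Polr2H, Polr2F, TfIIA-S and Taf4.

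The MADF and BESS domain family, to which Dip3 belongs, was bound at 6 of 10 genes, which were BEAF-32, Su(var)3-7, Dlip3, stwl, Coop and hng3. Dlip3 counts here through the peak that only replicate 3 listed, and BEAF-32 is counted among the insulator genes as well. Background regions also lay at the starts of 6 of 10 members of this family (odds ratio 8.63, Fisher's exact p = 0.0013, adjusted p = 0.0108 over the 25 lists). They were more frequent as well at anteroposterior patterning genes (9 of 23, odds ratio 3.7, exact p = 0.0039, adjusted p = 0.0195) and pan-neuronal genes (6 of 14, 4.31, exact p = 0.0109, adjusted p = 0.0455). Fewer lay at ribosomal protein genes (3 of 86, 0.206, exact p = 0.00117, adjusted p = 0.0108), where regions that overlap an IDR peak are left out of the background by definition.

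Cuticle protein, chemoreceptor, histone and dorsoventral patterning genes were bound less often than others. None of 93 cuticle protein genes had a bound start (0%, upper limit 3.89%), and chemoreceptor and odorant-binding protein genes had 3 of 228 (1.32%), which were Ir60e, Obp99b and Obp83g. Background regions were rarer too at chemoreceptor and odorant-binding protein genes (18 of 228, odds ratio 0.487, Fisher's exact p = 0.00186, adjusted p = 0.0116) and absent from histone genes (0%, upper limit 3.16%, exact p = 1.58e-08, adjusted p = 3.95e-07). No difference was detected for them at cuticle protein genes (12 of 93, odds ratio 0.849, exact p = 0.769, adjusted p = 0.916) or dorsoventral patterning genes (5 of 21, 1.79, exact p = 0.226, adjusted p = 0.425). Among histone genes 2 (1.74%) were bound, His2Av and His3.3B, and the rest are mostly near-identical repeats in which reads cannot be placed with certainty. None of 21 dorsoventral patterning genes was bound (upper limit 16.1%).

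Fisher's exact test over the 25 lists, with Benjamini-Hochberg adjustment, called 5 lists higher. By this exact test these were ribosomal proteins (odds ratio 14.1, p = 1.97e-30, adjusted p = 4.92e-29), cell cycle and DNA replication (3.44, p = 0.00105, adjusted p = 0.00526), and the MADF and BESS family (5.89, p = 0.0069, adjusted p = 0.0287). General transcription factors (2.39, exact p = 0.0129, adjusted p = 0.0407) and insulator, Polycomb and trithorax genes (3.14, p = 0.0178, adjusted p = 0.0495) followed. The 4 lower lists were chemoreceptors (0.0513, exact p = 1.05e-18, adjusted p = 1.31e-17), cuticle proteins (p = 9.3e-10, adjusted p = 7.75e-09), histones (0.0687, p = 3.23e-09, adjusted p = 2.02e-08) and dorsoventral patterning (p = 0.013, adjusted p = 0.0407). The dorsoventral call was lost at 200 and 1000 bp, with the most upstream start alone, in the upper 50% by signal and without each replicate, with adjusted exact p between 0.0738 and 0.372. The call on general transcription factors was lost without replicates 1, 2 and 3 (adjusted exact p = 0.279, 0.316 and 0.153), within 1000 bp (0.106), with the most upstream start alone (0.0705) and in the upper 50% by signal (0.197). The sets without replicates 1, 2 and 3 are smaller (2515, 2382 and 2733 peaks of 3741). A call lost in them need not rest on the replicate left out. The MADF and BESS call was lost without replicate 1 (adjusted exact p = 0.161), without replicate 3 (0.145), within 200 bp (0.738), with the most upstream start alone (0.0738) and in the upper 50% by signal (0.0787). The cell cycle call was lost within 200 bp (adjusted exact p = 0.165), and the insulator call within 1000 bp (0.106) and with the most upstream start alone (0.0961). The ribosomal protein call was kept throughout, but its odds ratio was 9.66, 8.20 and 6.51 without replicates 1, 2 and 3. It was 7.36 in the upper 50% by signal, 13.7 within 1000 bp, 16.0 with the most upstream start alone and 18.4 within 200 bp.

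**Figure D4:**
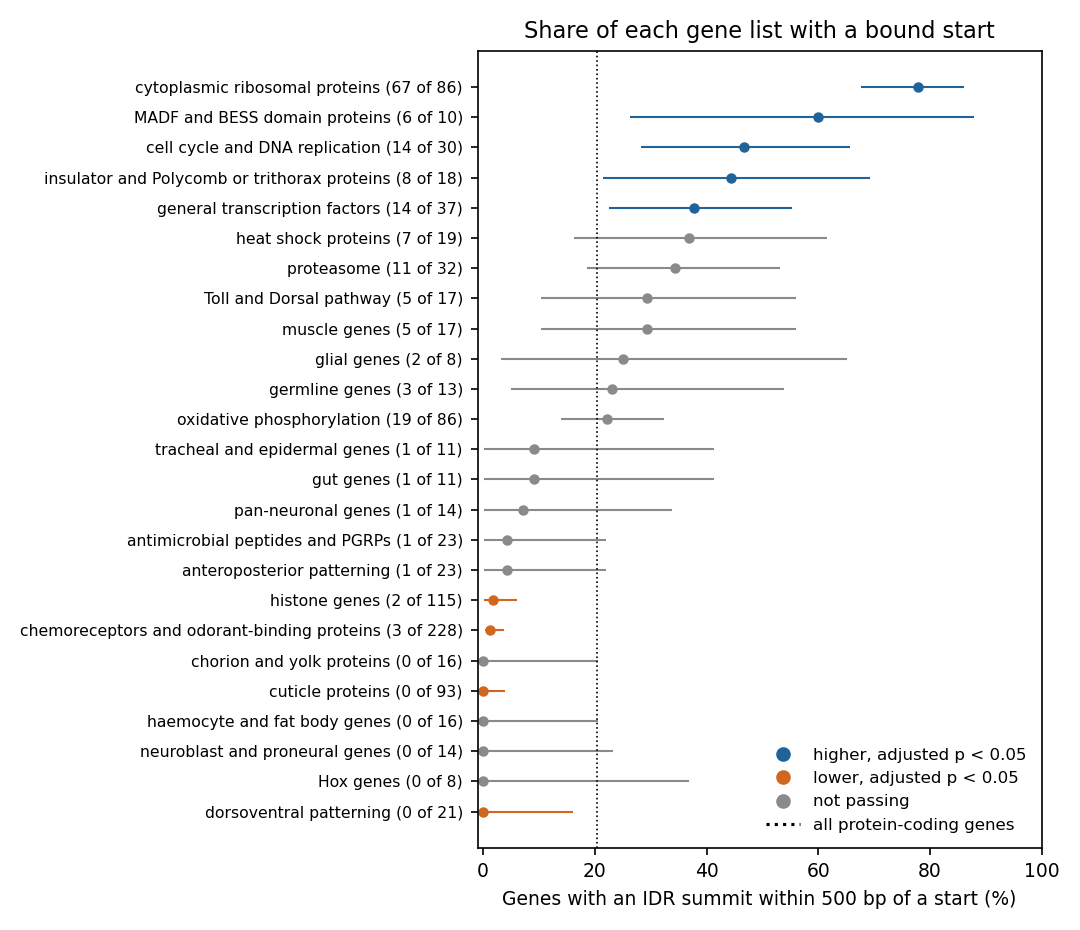
Share of genes with an IDR summit within 500 bp of a start (x axis, %) for each of the 25 gene lists (y axis, with counts), with exact 95% intervals. Blue and orange mark lists higher and lower at an adjusted p under 0.05, and the dotted line is the share of all protein-coding genes, 20.3%.

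The other lists did not pass. Of 17 genes of the Toll and Dorsal pathway 5 had a bound start (29.4%, 95% interval 10.3 to 56.0%, Fisher's exact p = 0.365, adjusted p = 0.466), namely cact, which encodes the inhibitor of Dorsal (signal 438), pll (176), Myd88, tub and pip. The peak at pll is also the peak that counts TfIIA-L as bound among the general transcription factors. Without replicates 1, 2 and 3 the odds ratio of the Toll and Dorsal list turned from 1.63 to 0.783, 0.847 and 0.776, in each case without a call. Antimicrobial peptide and PGRP genes had 1 of 23 (PGRP-LB), anteroposterior patterning genes 1 of 23 (bcd), and Hox genes 0 of 8. Heat shock protein genes had 7 of 19, led by Hsp27 (404) and Hsp83 (294), and the proteasome had 11 of 32, led by Rpn5 and Rpn3. Oxidative phosphorylation genes had 19 of 86 (22.1%), led by ND-ASHI and ND-MWFE. Among tissue lists, muscle genes had 5 of 17 (mbc, sls, Tm1, rols and Mef2), glial genes 2 of 8 (moody and loco) and germline genes 3 of 13 (bgcn, gcl and piwi). The germline gene nanos, which the symbol match missed, was bound as well, and with it the count was 4 of 14 (28.6%, exact p = 0.503, adjusted p = 0.571). Pan-neuronal genes had 1 of 14 (elav), tracheal and epidermal genes 1 of 11 (trh) and gut genes 1 of 11 (fkh). Neuroblast and proneural genes had 0 of 14, haemocyte and fat body genes 0 of 16, and chorion and yolk genes 0 of 16.

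Small non-coding RNA genes, apart from small nuclear RNA genes, had a summit near an annotated start less often than protein-coding genes. The number of starts per gene was not matched, and 13945 protein-coding genes had 19607 annotated starts. Whether the annotated starts of the small RNA genes are starts of transcription was not tested. Transfer RNA genes had a bound start in 13 of 290 cases (4.48%), small nucleolar RNA genes in 15 of 269 (5.58%), and precursor microRNA genes in 7 of 260 (2.69%). Ribosomal RNA genes had 0 of 99 (upper limit 3.66%), and these are repeats in which reads cannot be placed with certainty. Small nuclear RNA genes had 5 of 32 (15.6%), which did not differ from protein-coding genes (p = 0.661, adjusted p = 0.661 over 5 classes by Fisher's exact test). The other 4 classes were lower with adjusted p between 3.88e-16 and 5.37e-10.

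The X chromosome held 710 of 3723 IDR peaks on the 5 large arms (19.1%), against 14.6% of background regions (odds ratio 1.38, 95% interval 1.25 to 1.52, Fisher's exact p = 1.46e-10). In the replicates' own top lists the X share was 20.5%, 19.1% and 16.9%. Against random positions the difference was not detected (odds ratio 1.07, exact p = 0.149). Chromosome 4 carried 18 peaks, or 13.4 per Mb, and the large arms carried between 25.6 (3L) and 30.2 (X) per Mb.

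Several core promoter and insulator sequences, though not all, were more frequent at the summits than 500 bp away. The DNA replication-related element TATCGATA, bound by DREF, was in 2.89% of summit windows and 0.428% of flanks. Ohler motif 7 was in 8.85% against 2.86%, the BEAF-32 core CGATA in 20.4% against 12.2%, the CTCF site in 1.52% against 0.267%, Motif 1, bound by M1BP, in 0.936% against 0.187%, and Ohler motif 6 in 0.428% against 0.0802%. Since CGATA lies within TATCGATA, every window with TATCGATA is also counted for the BEAF-32 core. The initiator, another core promoter element, was in 8.18% of summit windows and 8.71% of flanks, and the core of the su(Hw) insulator site in 1.87% and 1.44%. The Rel site, which Dorsal and its relatives bind, was in 0.588% of summit windows and 0.829% of flanks. At promoters 4.75% of summit windows held TATCGATA, and elsewhere 0.376% did. For Ohler motif 7 these shares were 13.1% and 3.07%, and for the CTCF site 1.26% and 1.88%.

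With the exact McNemar test and adjustment over the 20 motifs, the 6 raised motifs named above had p between 5.33e-30 (adjusted p = 1.07e-28, Ohler motif 7) and 0.00443 (adjusted p = 0.00681, Ohler motif 6). The Rel site did not differ (exact p = 0.272, adjusted p = 0.32), nor did the TAGteam site of Zelda (p = 0.533, adjusted p = 0.561), the initiator (p = 0.434, adjusted p = 0.482) or the su(Hw) core (p = 0.178, adjusted p = 0.237). Against background summits of the same location class the initiator was lower (odds ratio 0.675, Fisher's exact p = 6.68e-07, adjusted p = 1.61e-06) and the su(Hw) core (1.54, p = 0.0289, adjusted p = 0.0385) and the CATATG E-box of Twist (1.43, p = 0.00735, adjusted p = 0.0105) were higher, though the latter did not differ from flanks (exact McNemar p = 0.239, adjusted p = 0.298). The location class does not match position. Promoter IDR summits had a median of −89 bp from the start and background promoter summits one of 1 bp, so their windows covered different DNA. The initiator result therefore cannot be told apart from window position. Against the same background summits Motif 1 (odds ratio 1.22, Fisher's exact test, adjusted p = 0.526) and Ohler motif 6 (1.16, adjusted p = 0.766) were no longer called. The call on Motif 1 was also lost without replicate 1 (adjusted exact p = 0.0637) and in the upper 50% by signal (0.182). Its ratio of summit-only to flank-only windows was still 2.82 and 2.71 there, down from 4.73. The call on Ohler motif 6 was lost without replicates 1, 2 and 3 (adjusted exact p = 0.132, 0.209 and 0.173), in shorter windows (0.292) and with flanks 300 bp away (0.075). Summit windows were poorer in G and C than flanks, with 36.4% ± 9.23 (SD over 3741 windows) against 44.3% ± 10.3. Some calls changed with this composition. The TATA box (5.69% against 3.02%) was higher than in flanks but did not differ from shuffled summit windows (5.85%, exact McNemar p = 0.797, adjusted p = 0.838). The GATA site (20.9% against 16.2%) and the homeodomain core (7.94% against 5.88%) were higher than in flanks but lower than in shuffled windows, at 23.1% and 9.92% (exact test, adjusted p = 0.0312 and 0.00457). The GAGA element (9.97% against 15.4%), the Adf1 site (2.25% against 5.75%) and the E-box (38.0% against 41.8%) were lower than in flanks but higher than in shuffled windows, at 7.70%, 1.28% and 32.4% (exact test, adjusted p = 0.000615, 0.0038 and 2.45e-07).

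**Figure D5:**
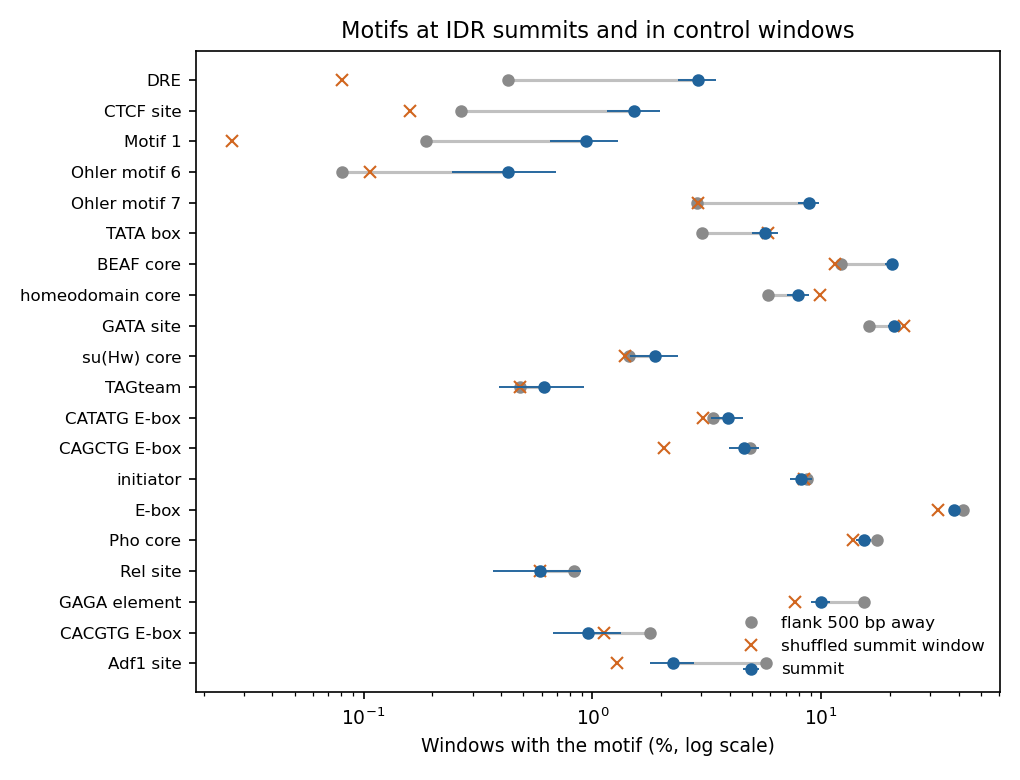
Share of windows with each of the 20 motifs (x axis, %, log scale) at IDR summits (blue, with exact 95% intervals), in flanks 500 bp away (grey) and in shuffled summit windows (orange crosses). DRE, at 2.89% of summits, lies far from both controls, and the TATA box at 5.69% lies on its shuffled value of 5.85%.

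An undirected search for words returned the TATCGATA family and a word, CAACACTG, that matches none of the 20 motifs in full. It differs from Ohler motif 7 (CAKCNCTR, with K for G or T) at a single base. Of 32896 words of 8 bases, 604 were more and 446 less frequent at summits than in flanks (exact McNemar test, adjusted p under 0.05). Against background summits of the same location class 564 were more and 579 less frequent by Fisher's exact test. Of 2080 words of 6 bases 475 were more and 787 less frequent at summits than in flanks. Mean GC content was 36.4% in summit windows, 44.3% in flanks and 45.1% at background summits. The counts of called words were not corrected for this difference. The word with the largest ratio was CAACACTG, which was in 106 summit windows and 10 flanks (exact p = 2.16e-21, adjusted p = 7.12e-17) and in 8 shuffled windows. It was in 4.75% of promoter summits and 0.251% of other summits. The next were TATCGATA (108 against 16 windows), AACTATCG (85 against 12), ATCGATAG (116 against 19), ATCGATAA (86 against 18) and ACTATCGA (75 against 19). The remaining 4 of the 10 words with the largest ratios, TTTTAAAA, CAATTTAA, AAATGTTA and ATTTTATA, were also common in shuffled windows, the first 3 in 78, 69 and 70 of them. Among words of 6 bases CGATAG (301 against 108 windows), TATCGA (376 against 143) and ACACTG (366 against 145) led, followed by AACTAT, ACAGTG, TTTAAA, AACACT, TTAAAA, AAATAT and CTAATA. Shuffled windows held CGATAG 72 times, TATCGA 131 times and ACACTG 122 times, but CTAATA more often than summits did (300 against 260 windows), and TTAAAA (982 against 1067) and TTTAAA (536 against 669) nearly as often.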

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

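In the dm3 lists, which the comparisons above use only for counts and overlaps, replicate 3 had 4 regions with a q value of 0.01 or less outside the main chromosome arms, 1 more than the 3 that a count of 0 allows. It has more regions at that q value than the other replicates, and the share outside the arms, 0.048% of 8327 regions (95% interval 0.0131 to 0.123%), was close to the 0.0415% of 2408 regions in replicate 1 and the 0.0318% of 3142 in replicate 2, so the count does not set replicate 3 apart. They lay on unplaced heterochromatin of the X (2) and of 3L (1) and on the mitochondrial sequence (1). The pooled dm3 list had 3 such regions, replicates 1 and 2 had 1 each, and the dm3 IDR set had 0. This look outside the arms was chosen after the lists had been seen.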

How the results depend on the processing

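The shuffled windows, the X share without each replicate and the completed gene lists were chosen after seeing the data. Of 80 alternative values for the main results 64 kept their side of the threshold or stayed within their margin, which is the spread between replicates or, for counts, 1.5 times. The share of IDR peaks in all replicates (58.7%) was 43.5% at reciprocal 50% overlap, 51.8% for summits within 100 bp, 81.4% with top lists of double length, 91.0% with the whole lists, and 63.7 to 73.1% leaving out 1 replicate each. Of the 3741 peaks, 1871 form the upper 50% by signal and 2382 to 2733 were in both other top lists when 1 replicate was left out. The Spearman correlation of signal between replicates ranged from 0.650 to 0.803 over the pairs. The promoter share was 44.2% at 200 bp and 67.0% at 1000 bp, which follows from the window. The X odds ratio was 1.07 against random positions, and the cause was not tested. Of 9 called gene lists 5 were called with the most upstream start alone (2 higher and 3 lower), 7 without replicate 2, and 6 at 200 bp, at 1000 bp, in the upper 50% by signal and without replicates 1 and 3. Shorter and longer windows called 139 words of 8 bases (100 higher, 39 lower) and 3192 (1486 higher, 1706 lower), so the balance turned in longer windows, and the cause was not tested.

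Against shuffled summit windows, which share the summits' base composition, 8 motifs changed the direction of their ratio, though CAGCTG had not been called against flanks (exact test, adjusted p = 0.622) and TATA (0.838) and Pho (0.0738) were not called against shuffled windows. The ratio of windows with the motif at the summit alone to those in the control alone became 1.38 (GAGA), 1.32 (E-box), 2.32 (CAGCTG), 1.79 (Adf1), 1.14 (Pho), 0.969 (TATA), 0.772 (homeodomain) and 0.872 (GATA). Among 358 values of single lists and motifs, 288 kept direction and call, 18 turned but were called on neither side, 40 lost the call and 4 gained one in the same direction, and the remaining 8 are the motifs just named, of which 5 were called in both directions, 2 lost the call and 1 gained it. Unknown read depth leaves weak peaks, of which 9.95% of the lowest quartile were in all top lists, the least certain.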

Other observations

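The gene lists, the most upstream start and the windows at unbound starts for bound summits were fixed before their results were seen, and the other tests in this part, and the use of the lists to weigh explanations, were chosen afterwards. Promoter summits often lay nearest to a gene with a divergent neighbour. Of 2147 promoter IDR summits, 1144 (53.3%) lay nearest to a gene that has another protein-coding start on the opposite strand within 1 kb upstream, against 28.6% of 2018 background promoter summits (odds ratio 2.84, 95% interval 2.5 to 3.23, Fisher's exact p = 2.59e-59). Counted by gene, 66.9% of bound and 28.4% of other genes had such a neighbour, a count in which a single summit can mark both genes. Whether the summit lay between the divergent starts was not tested. Position was not matched, as 84.9% of IDR and 49.6% of background promoter summits lay upstream of the start.

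Away from starts, some long genes held many summits. The gene shn, which encodes a zinc finger partner of the Dpp signalling pathway, held 12 IDR summits more than 500 bp from a start over 58.3 kb (2R, 11159086 to 11217394). The nuclear receptor gene Hr4 and tara held 9 each, and CHES-1-like, Raf, Tlk, sbb and ush held 8 each. At ribosomal protein promoters the sequences differed from those at other bound promoters. TATCGATA was in 15 of 67 windows (22.4%) against 4.18% of 2080 (odds ratio 6.61, p = 2.26e-07, adjusted p = 4.75e-06 over 21 sequences by Fisher's exact test). Motif 1 was in 8.96% against 1.3% (exact test, adjusted p = 0.00294) and the BEAF-32 core in 53.7% against 25.9% (adjusted p = 2.07e-05). The BEAF-32 core CGATA lies within TATCGATA, so its result is not independent of that for TATCGATA. The core outside TATCGATA was not tested. Ohler motif 6 was in 5.97% against 0.529% (exact test, adjusted p = 0.00479), and the initiator went the other way, with 0 of 67 (upper limit 5.36%) against 7.93% (exact test, adjusted p = 0.0352). Summit position relative to the start was not matched between these promoters. CAACACTG was in 2.99% against 4.81% (exact test, adjusted p = 0.85).

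The IDR peaks at Dlip3 and pAbp stood in the list of replicate 3 alone. Whether these peaks were absent from replicates 1 and 2 at random stays open. The stretch around them was delimited after the lists were seen, and most of them are neighbours at pAbp and not separate cases. These 4 peaks ranked 425, 1512, 1972 and 3237 in the IDR set, and the absent peaks elsewhere ranked from 2864 to 3732, a range that holds only the last of these. Only the 4 IDR peaks of the 21.8 kb stretch lay in so long a gap of replicates 1 and 2. A test of the grouping did not decide the question either. In a one-sided permutation test, peaks within 2 kb of a neighbour were joined, and the 10 absent groups were shuffled among 3133 groups by signal quartile. At most 2 then fell within any 15 kb, as many as here (permutation p = 0.0143), but this was the last of 3 forms of the test tried, all with a distance set after the peaks were seen. The amount of DNA from the stretch in each library and the part of the transgene were not measured by peak lists, and no biological explanation was tested.

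A high share of ribosomal protein genes had a bound start. The number of annotated starts was argued against as its cause by the most upstream start alone, with an odds ratio of 16.0. The oxidative phosphorylation list did not show such a share. Its odds ratio had an upper limit of 1.85, below the lower limit of 8.48 for ribosomal proteins. Equal binding at all abundantly transcribed genes could not be weighed by this list, because transcription was not measured here. Both limits are those of the full IDR set. Without replicates 1, 2 and 3 the ribosomal protein odds ratio was 9.66, 8.20 and 6.51, and that of oxidative phosphorylation 1.05, 1.03 and 1.23. Calling of regions at these starts at any strength stays open, because at starts without an IDR summit background regions were too few to tell (2 of 19 ribosomal protein genes, odds ratio 0.595, 95% interval 0.137 to 2.58). Unspecific recovery also stays open, as control libraries were not analysed here, and no biological explanation was tested.

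Promoter summits were poor in G and C. Position relative to the start was argued against as the whole cause, since windows at the same distances from unbound starts had a mean GC content 3.05 percentage points higher (40.4% against 37.4%, 95% interval of the difference 2.44 to 3.65). A library or caller that favours such DNA in all listed regions alike was argued against by background promoter summits, whose mean GC content was 2.55 points above that at the same distances from unbound starts (95% interval 1.88 to 3.22). A bias that raises the signal of such DNA stays open, because background regions were chosen for their low signal. For IDR summits at all locations, mean GC content was 34.4% in the strongest quartile by signal. It was 36.6%, 37.2% and 37.4% in the following quartiles, down to the weakest. A bias that acts on strong regions alone was not tested. No biological explanation was tested.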
